A study of Bos taurus with 45 samples.

How the data were processed

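Gene expression was measured in liver biopsies of 45 cows on Agilent 2-colour bovine oligonucleotide arrays, 1 array per cow. The labels name every array as a separate biological replicate of 1 of 4 groups, which combine 2 or 1 milkings a day (2X, 1X) with adequate feeding or feeding at 60% of requirements (AF, UF). The design text speaks of 48 enrolled animals and of 45 in one sentence and 46 in another, and 45 arrays were analysed here. Per the labels' protocols, 150 ng of total RNA of each sample was labelled with Cy5 and hybridised together with a Cy3-labelled pool of all samples, with no dye swap.

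The authors scanned each array and deposited, per the file headers, the output of Agilent Feature Extraction 10.7.3.1, which gives the median intensity of each spot and of its local background in both channels. The same deposited files hold a log10 ratio of red over green after the scanner software's own background subtraction and dye normalization, which was used as an alternative. A deposited value table of the series holds log2 ratios for 10293 probes. How the authors made it is not given in the sources used here. Set against the scanner ratio of the same arrays it ran in the opposite direction (r from -1 to -0.991, slope from -1 to -0.984), so it was turned before use. Its scale was thereby found to be log2 of reference over sample, and its column medians lay between -0.0142 and 0.048.

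Arrays were processed with R 4.3.3 and limma 3.58.1. The plan named the mean spot signal, which the files do not hold, so the median signal and median background were used. Background was corrected with normexp and an offset of 50, and ratios were normalized by loess within each array, with control spots and spots marked as outliers at weight 0. From 1 to 244 spots per array were so marked. The 42990 spots that are not controls were averaged over the 21475 probes. A probe was tested if it was well above background in the sample channel on at least 10 arrays, which left 15811 probes. Ratios to a common pool are relative within a gene, and loess assumes that most transcripts do not change. The median change over all probes was 0.00512 for feeding, but loess itself brings that value near 0, so it does not test the assumption. The dyes are stated in the labels, so the direction of every ratio was taken from them, although replicate 1 of 1XUF and replicate 12 of 1XAF correlated negatively (r = -0.358 over all probes). On 45 of 45 arrays the red channel lay farther from its mean over the arrays than the green channel, which argues against swapped dyes.

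Gene names came from the RefSeq accession of each probe, matched without versions to a RefSeq gene table of assembly ARS-UCD2.0. Of the 9579 probes with such an accession 7191 were named, giving 6789 symbols, and 14284 probes stayed unnamed and are counted but not named in the results. CPT1A, IGF1 and FASN were not among the named probes. The array was designed on an older assembly, so no coordinates are given. For 279 of 5782 tested genes with more than 1 probe, the probe with the highest mean brightness was used, and 0 genes had probes called in opposite directions.

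One limma model with 4 group means was fitted to all arrays, with contrasts for feeding, for milking frequency, for their interaction and for each factor within the levels of the other. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Gene lists were tested with camera at an inter-gene correlation of 0.01, adjusted over the 29 lists with at least 5 measured members, and again with an estimated correlation. The lists covered 23 pathways and 9 cell types. The pathways were gluconeogenesis and propionate entry, fatty acid oxidation, ketone body synthesis, PPARA targets, fatty acid and triglyceride synthesis, cholesterol synthesis, bile acid synthesis and transport, lipoprotein assembly and export, the growth hormone and IGF axis, the urea cycle and amino acid catabolism, the acute phase response, the interferon response, the unfolded protein response, NRF2 and antioxidant defence, xenobiotic metabolism, glucocorticoid targets, the circadian clock, oxidative phosphorylation, cytosolic ribosomal proteins, the proteasome, the cell cycle, extracellular matrix, and autophagy and lysosome. Named genes are the 12 with the largest rise and the 12 with the largest fall that passed, the 5 with the smallest p where fewer than 5 passed, the 3 largest each way within a level, the 4 members of each described list with the smallest p, and 10 genes of energy metabolism set beforehand. The milk protein transcripts and other mammary markers lie outside that rule and were chosen after their values were seen. Groups, model, thresholds, lists, this rule and the alternatives other than those listed next were chosen before the data were examined. Scan day as a block, each scan day alone, and leaving out replicate 1 of 2XUF or replicate 1 of 1XUF were chosen after seeing the data, as was the permutation test of list means (100000 permutations).

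The arrays came from 12 slides and 2 scan days. Of the slides 1 held a single array, 1 held 3 of the groups and the others all 4. Scan day 1 held 8 arrays of each group, and scan day 2 held 4 of 2XAF, 2 of 2XUF, 4 of 1XAF and 3 of 1XUF. The alternatives, whose effect the closing part gives, covered normalization of brightness between arrays, background correction, the scanner's own ratio, the deposited value table, the sample channel alone, the filter on dim probes, spots marked as outliers, slide and replicate number as blocks, array weights, the variance model, the samples in the fit and the list test. The first of these leaves the log ratios unchanged, so normalization of the ratios between arrays was not examined.

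The fits were tested on simulated data built from the real spread. A feeding change of 0.25 on the log2 scale was recovered for 79.1% of 67 changed probes, one of 0.5 for 94.0% and one of 1 for 98.5% of 66, with 9 false calls among 15611 unchanged probes. The list test recovered a feeding list of 20 genes shifted by 0.2 in 50 of 50 draws and called 4 of 1400 unshifted lists. That simulation left out correlation between genes, which the regroupings of the real arrays keep. Those regroupings gave a median of 6 called lists, so 4 of 1400 does not describe the list test on the real arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.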

Results

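Liver biopsies of 45 lactating cows (Bos taurus) were hybridised to 2-colour oligonucleotide arrays, 1 cow per array. The cows were milked 2 times a day (2X) or 1 time a day (1X). They were adequately fed (AF) or under-fed (UF, at 60% of requirements) for 3 weeks from about week 5 after calving, and the liver was then sampled. The groups held 12 arrays (2XAF), 10 arrays (2XUF), 12 arrays (1XAF) and 11 arrays (1XUF). Each array carried RNA of 1 cow in the red channel and a pool of all samples in the green channel, so that every value is a log2 ratio of a sample to that pool. Between 14019 and 15963 of 21475 probes per array (median 15202) were well above background in the sample channel, and none was saturated in that channel. The number of cows limits the precision of each comparison. Differences are given as UF minus AF for feeding and 1X minus 2X for milking, and the deposited value table of the same arrays runs in the opposite direction (reference over sample).

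The main axis of variation among the livers followed feeding. On the first principal component, which held 13.3% of the variance, 20 of 21 under-fed arrays lay above 0 and 23 of 24 adequately fed arrays lay below 0. Mean scores on that component were -7.44 ± 5.03 (SD, n = 12) in 2XAF, -10.12 ± 5.50 (n = 12) in 1XAF, 10.29 ± 7.04 (n = 10) in 2XUF and 9.81 ± 5.75 (n = 11) in 1XUF. The second component held 9.51%, and its lowest score, -43, belonged to replicate 1 of 2XUF.

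**Figure D1:**
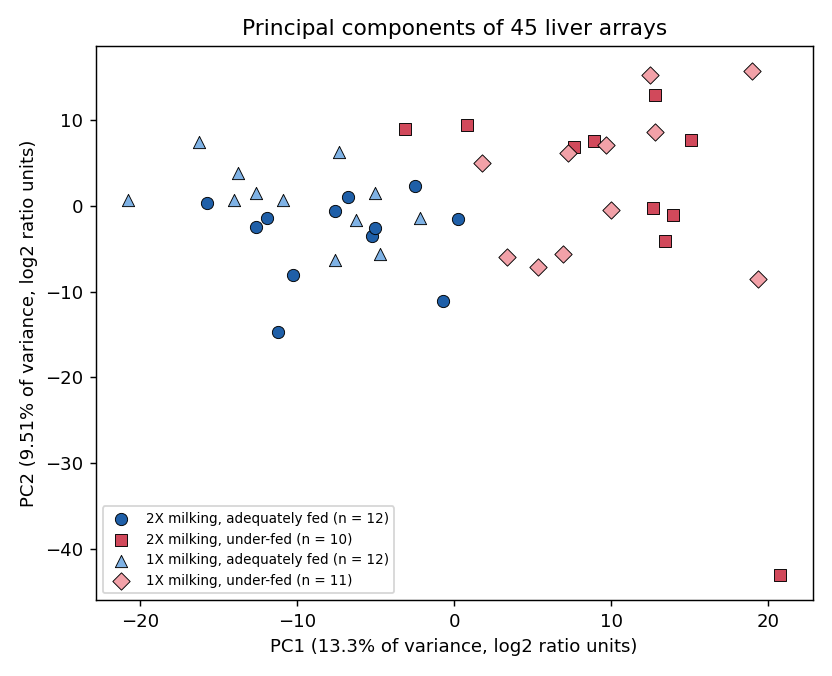
Scores of the 45 arrays on the first and second principal components of the log2 ratios (axes in log2 ratio units, with the share of variance), with 1 point per cow and symbols for the 4 groups. The first component holds 13.3% of the variance and parts 20 of 21 under-fed arrays, above 0, from 23 of 24 adequately fed arrays, below 0.

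The comparison of under-fed with adequately fed cows, averaged over both milking frequencies, asked which liver transcripts responded to restriction. The largest rises were those of GPX3, ANGPTL4 and MT2A and the largest falls those of SCD, THRSP and FADS2. GPX3, a secreted glutathione peroxidase, rose by 2.16 on the log2 scale (SE 0.26, 21 UF and 24 AF arrays, limma adjusted p = 9.92e-08), which is 4.48-fold. ANGPTL4, an inhibitor of lipoprotein lipase, rose by 2.07 (SE 0.20), and MT2A, a metallothionein, by 1.64 (SE 0.22). SCD, the stearoyl-CoA desaturase, fell by 2.14 (SE 0.33, adjusted p = 6.08e-06), THRSP, a regulator of lipogenic transcription, fell by 1.87 (SE 0.21) and FADS2, a fatty acid desaturase, fell by 1.53 (SE 0.22). Each of GPX3, ANGPTL4 and MT2A was higher in the under-fed arrays on 11 of 11 slides, SCD and THRSP were lower on 11 of 11, and FADS2 was lower on 10 of 11.

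The other rises among the 12 largest were APOA4 (1.45, SE 0.33) and APOA1 (1.25, SE 0.19), apolipoproteins of high-density particles and chylomicrons, and INHBA (1.37, SE 0.14), which encodes the subunit of activin A. PDK4, which blocks the entry of pyruvate into mitochondrial oxidation, rose by 1.13 (SE 0.17) and PLIN2, the coat protein of lipid droplets, by 1.09 (SE 0.15). MOB3C rose by 1.12, SLC25A34, of the mitochondrial carrier family, by 1.02, MAT2A, a methionine adenosyltransferase, by 0.99, and CREB3L3, a transcription factor of the fasted liver, by 0.96 (SE 0.09). MAT2A had the smallest p of the named genes (adjusted p = 5.84e-11, higher on 11 of 11 slides). Among the 12 largest falls were TMED6 (-1.31), FABP1, the liver fatty acid binding protein (-1.30, SE 0.19), ACSS2, which activates acetate to acetyl-CoA (-1.28, SE 0.31), and the fatty acid elongase ELOVL6 (-1.07, SE 0.13). OSGIN1 (-0.86), DIRAS3 (-0.86), HSD17B12, an enzyme of fatty acid elongation (-0.85), IL1R2, a decoy receptor for interleukin 1 (-0.84), and ABCG8, a sterol exporter (-0.82), completed the list. The adjusted p of these 24 genes ranged up to 0.00217. Sizes moved by over 1.5 times for FADS2 (-1.0) and FABP1 (-0.69) with the sample channel alone and for GPX3 (1.43) and ACSS2 (-0.50, adjusted p = 0.785) on scan day 2 alone.

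By limma 2894 of 15811 tested probes (18.3%) passed an adjusted p of 0.05, of which 1593 were higher and 1301 lower in under-fed cows. They included 1206 named genes. Changes were mostly small, with a median size of 0.195 on the log2 scale, and 137 probes changed by over 1.5-fold and 35 by over 2-fold. With the slide as a block 3081 probes passed and with scan day as a block 2916. On scan day 1 alone (32 arrays) 1941 passed and on scan day 2 alone (13 arrays) 80, and with the sample channel alone, without the pooled reference, 1858.

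**Figure D2:**
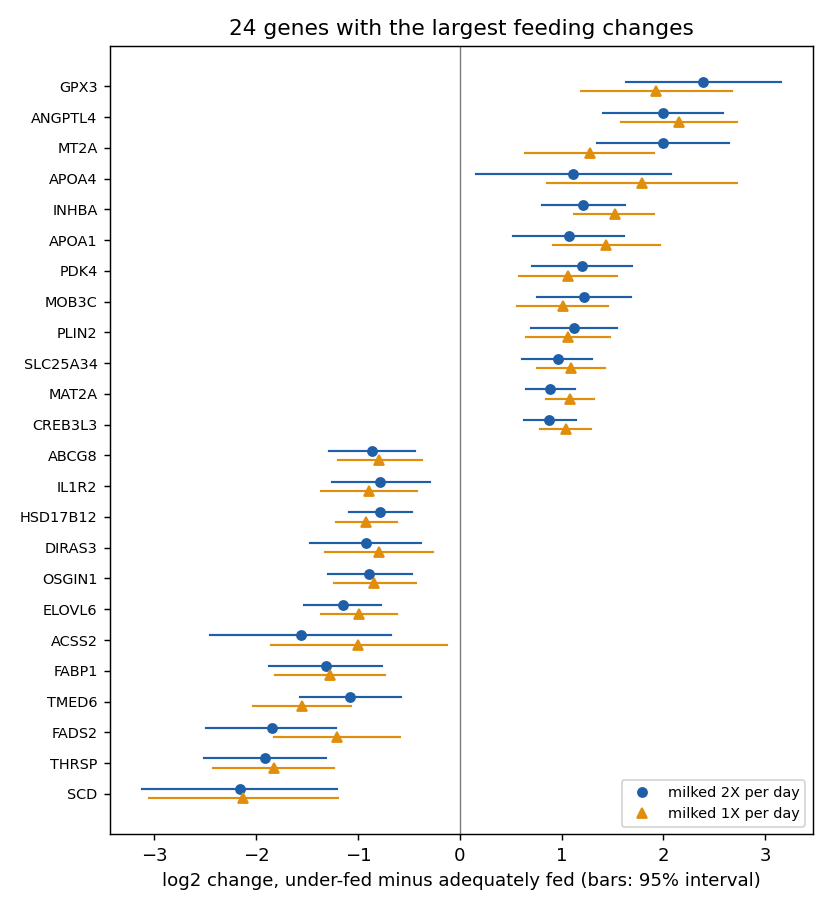
Log2 change between under-fed and adequately fed cows (horizontal axis, bars give the 95% interval of the limma fit) for the 24 genes with the largest feeding changes, at 2X milking (circles, 10 and 12 arrays) and at 1X milking (triangles, 11 and 12 arrays). Both estimates of each gene lie on the same side of 0, from GPX3 (2.39 at 2X and 1.93 at 1X) to SCD (-2.16 and -2.13). The genes were chosen by the mean of both changes, which favours equal signs.

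Among the lists of genes fixed in advance, the transcripts that code for oxidative phosphorylation, the respiratory chain and ATP synthase, fell together under restriction. Of 60 measured members 32 fell and none rose, and 38 fell when adjusted over the list alone. The median change was small (-0.13), and the list mean was lower in the under-fed arrays on 11 of 11 slides. The ATP synthase subunits ATP5MC1 (-0.31, SE 0.04), ATP5MC3 (-0.34, SE 0.05) and ATP5F1A (-0.30, SE 0.04) and the cytochrome c oxidase subunit COX7A2 (-0.30, SE 0.04) had the smallest p. The list stood below the other genes by camera with adjusted p = 2.66e-14, and with adjusted p = 0.0281 with an estimated correlation.

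Targets of PPARA, the transcription factor that senses fatty acids in liver, stood above the other genes (camera adjusted p = 0.00248, and adjusted p = 0.487 with an estimated correlation). Of 19 measured members 7 rose, 1 fell (FABP1) and 11 did not pass, with the same counts when adjusted over the list alone. Besides ANGPTL4, PLIN2 and CREB3L3, SLC22A5, the carnitine transporter, rose by 0.81 (SE 0.09). Fatty acid and triglyceride synthesis stood below the other genes (adjusted p = 0.00248, and adjusted p = 0.339 with an estimated correlation). Of its 18 members 8 fell, 2 rose and 8 did not pass (9 and 2 adjusted over the list alone), led by THRSP, ELOVL6, FADS2 and SCD. SREBF1, which encodes the transcription factor of lipogenesis, differed by -0.12 (SE 0.10, adjusted p = 0.454).

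Cholesterol synthesis also stood below the other genes (adjusted p = 0.004, and adjusted p = 0.85 with an estimated correlation). Of 17 members 6 fell and none rose (7 adjusted over the list alone), among them the sterol enzymes TM7SF2 (-0.33), HSD17B7 (-0.51), MSMO1 (-0.60) and EBP (-0.25, adjusted p = 0.0206, or 0.0569 with the slide as a block). The urea cycle and amino acid catabolism list stood lower (adjusted p = 0.00759, and adjusted p = 0.487 with an estimated correlation): 8 of 26 members fell and none rose (9 and 1 adjusted over the list alone). PRODH, which oxidises proline, fell by 0.61 (SE 0.10), TDO2, which degrades tryptophan, by 0.40, and the arginases ARG2 and ARG1 fell by 0.58 and 0.40.

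Chaperones and other targets of the unfolded protein response stood above the other genes (adjusted p = 0.0218, and adjusted p = 0.719 with an estimated correlation). Of 14 members 5 rose and none fell, with the same counts adjusted over the list alone. HSPA5, the main chaperone of the endoplasmic reticulum, rose by 0.91 (SE 0.14), CRELD2 by 0.74 (SE 0.12), DNAJB11 by 0.67 (SE 0.11) and the transcription factor XBP1 by 0.44 (SE 0.09), and the list mean was higher in the under-fed arrays on 11 of 11 slides. Without replicate 1 of 2XUF the adjusted p of the unfolded protein response list was 0.0669 and with array weights 0.0907, while its mean change was 0.189 and 0.185 against 0.217 with all arrays weighted alike. Glucocorticoid targets stood higher (adjusted p = 0.0173, and adjusted p = 0.487 with an estimated correlation), with 5 of 13 members up and none down (6 and 1 adjusted over the list alone). Besides MT2A and PDK4, which are shared with other lists, the phosphatase DUSP1 rose by 0.94 (SE 0.19) and NFKBIA, an inhibitor of NF-kappa-B, by 0.39 (SE 0.11), or 0.27 on scan day 1 alone (adjusted p = 0.219).

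The acute phase response list stood above the other genes (adjusted p = 0.0218, and adjusted p = 0.85 with an estimated correlation), with 4 of 19 members up and none down, also adjusted over the list alone. IL1RN, the interleukin 1 receptor antagonist, rose by 0.56 (SE 0.09), HAMP, which encodes hepcidin, by 0.74 (SE 0.14), LBP, the lipopolysaccharide binding protein, by 0.73 (SE 0.20), and ITIH3 by 0.41 (SE 0.14, adjusted p = 0.0352). One array stood apart in this list: its mean log2 ratio was 1.61 in replicate 1 of 2XUF, against 0.55 in the next array of that group. Without that array the adjusted p was 0.118 for the acute phase response list and 0.0537 for ITIH3, and with array weights 0.118 and 0.14.

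Gluconeogenesis and propionate entry showed no shared direction (adjusted p = 0.329). Of 20 members 4 rose and 6 fell (4 and 8 adjusted over the list alone). PC, pyruvate carboxylase, rose by 0.53 (SE 0.10, adjusted p = 0.000156), while MDH1 (-0.37), GPI (-0.31) and TPI1 (-0.34), enzymes also used in glycolysis or malate transfer, fell. PCK1 (0.01, SE 0.14, adjusted p = 0.982) and G6PC1 (0.09, SE 0.11, adjusted p = 0.635), which encode the later control steps of gluconeogenesis, did not pass. Fatty acid oxidation showed no shared direction either (adjusted p = 0.86), with 4 of 19 members up and 1 down, also adjusted over the list alone. ACSL1 (0.65, SE 0.11), ACAA1 (0.28) and CROT (0.33, on scan day 1 alone adjusted p = 0.132) rose and DECR1 fell by 0.40 (SE 0.06). The median of that list was -0.008 while its mean was 0.035 and the test leaned up. The ketone body synthesis list held only 4 measured members and was not tested.

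The remaining metabolic lists held changes in both directions. In lipoprotein assembly and export (adjusted p = 0.487) APOA1, APOA4 and APOC2 (0.40, SE 0.10) rose and APOH (-0.37, SE 0.07, or -0.17 with adjusted p = 0.0934 with the sample channel alone) fell, and 8 of 12 members did not pass, also adjusted over the list alone. In bile acid synthesis and transport (adjusted p = 0.487) CYP39A1 (-0.62, SE 0.08) and SLCO1B3 (-0.19, with the sample channel alone adjusted p = 0.125) fell, AKR1C4 (0.49, SE 0.10) rose and 5 of 8 did not pass, also adjusted over the list alone. SLC10A1, the bile acid importer, differed by 0.14 (adjusted p = 0.338), and by 0.22 without replicate 1 of 2XUF (adjusted p = 0.0443). In the growth hormone and IGF axis (adjusted p = 0.945) PRLR (0.52, SE 0.12), IGFBP4 (0.30) and IGFBP2 (0.49) rose and CISH (-0.30) fell, with 3 of 11 members up and 2 down (3 each adjusted over the list alone). GHR differed by -0.22 (SE 0.10, adjusted p = 0.127). The median of that list was -0.005, its mean 0.006.

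In NRF2 and antioxidant defence (adjusted p = 0.487) 4 of 26 members rose and 5 fell (4 and 6 adjusted over the list alone). GPX3 and MT2A led the rises, and FTH1, the ferritin heavy chain (-0.38, SE 0.07), and GSTA4 (-0.67, SE 0.13) fell. Its median was -0.064, its mean 0.022, and the test leaned down. In xenobiotic metabolism (adjusted p = 0.331) 1 of 17 members rose and 3 fell, also adjusted over the list alone. UGT2B10 rose by 0.85 (SE 0.25), and AOX1 (-0.65, SE 0.11), CYP2C87 (-0.72, SE 0.18) and CYP2C89 (-0.54, SE 0.15) fell. In the circadian clock list (adjusted p = 0.487) 3 of 6 members rose and none fell (3 and 1 adjusted over the list alone). CRY1 rose by 0.39 (SE 0.07), and CLOCK (0.07, adjusted p = 0.0423) and NFIL3 (0.15, adjusted p = 0.0434) passed narrowly, and not with array weights (0.0858 and 0.0669). DBP differed by -0.20 (adjusted p = 0.0674, or 0.0261 with the slide as a block).

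Lists of cell type markers gave no difference between feeding levels. Adjusted p was 0.876 for hepatocyte markers, 0.953 for macrophage, 0.487 for T and NK cell, 0.557 for neutrophil, 0.459 for endothelial cell, 0.86 for stellate cell and fibroblast and 0.459 for bile duct cell markers, and the B and plasma cell and red blood cell lists held only 4 measured members each. Of 9 hepatocyte markers 2 rose (APOA1 and ASGR1, 0.24) and 2 fell (TF, transferrin, -0.52, and TTR, transthyretin, -0.43), also adjusted over the list alone. Replicate 1 of 1XUF stood apart in the hepatocyte mean, at -0.763 against 0.049 in the next array of that group (group SD 0.329). For feeding the hepatocyte list passed in 0 of 18 alternatives, the one without that array included. Of the macrophage, T and NK cell and neutrophil markers none passed, and 1 of 6 endothelial and 1 of 5 bile duct cell markers rose, in each case also adjusted over the list alone. Of the stellate cell and fibroblast markers LRAT fell by 0.36 (SE 0.09) and 11 of 12 did not pass, while adjusted over the list alone 1 fell and none rose.

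Altogether camera called 8 of 29 lists for feeding, 4 up and 4 down, and 1 of them with an estimated correlation. The mean log2 ratio of each list per array was also compared by a two-sided permutation test, chosen after the camera results were seen. That test asks whether a list mean changed at all, while camera asks whether a list moved more than the other genes. The permutation test gave adjusted p = 0.000145 for oxidative phosphorylation, PPARA targets, fatty acid and triglyceride synthesis and unfolded protein response, 0.00058 for glucocorticoid targets, 0.00324 for urea cycle and amino acid catabolism, 0.0063 for lipoprotein assembly and export, 0.031 for acute phase response and 0.109 for cholesterol synthesis. Of 100 regroupings of the arrays, 32 gave camera calls for as many lists as feeding did, and the median of the others was 6 lists.

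By slide and scan day, oxidative phosphorylation kept its direction with adjusted p = 4.39e-14 with slide as a block, 2.18e-14 with scan day as a block, 3.94e-13 on day 1 and 3.96e-10 on day 2. PPARA targets gave 0.00506, 0.00275, 0.00294 and 0.00153 in the same order, and fatty acid and triglyceride synthesis 0.00506, 0.00275, 0.00116 and 0.12. Cholesterol synthesis gave 0.0174, 0.00784, 0.000277 and 0.789, the last with the test leaning up, and urea cycle and amino acid catabolism 0.00506, 0.00761, 0.00138 and 0.691. Unfolded protein response gave 0.0368, 0.0219, 0.0359 and 0.0892, glucocorticoid targets 0.0368, 0.0231, 0.143 and 0.00137, and acute phase response 0.0368, 0.0244, 0.014 and 0.789. Where a call was lost on 1 scan day, the median change was -0.127 for fatty acid and triglyceride synthesis (against -0.121 over all arrays), 0.046 for unfolded protein response (0.036) and 0.122 for glucocorticoid targets (0.128), but -0.005 for cholesterol synthesis (-0.321), -0.064 for urea cycle and amino acid catabolism (-0.117) and 0.088 for acute phase response (0.13).

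**Figure D3:**
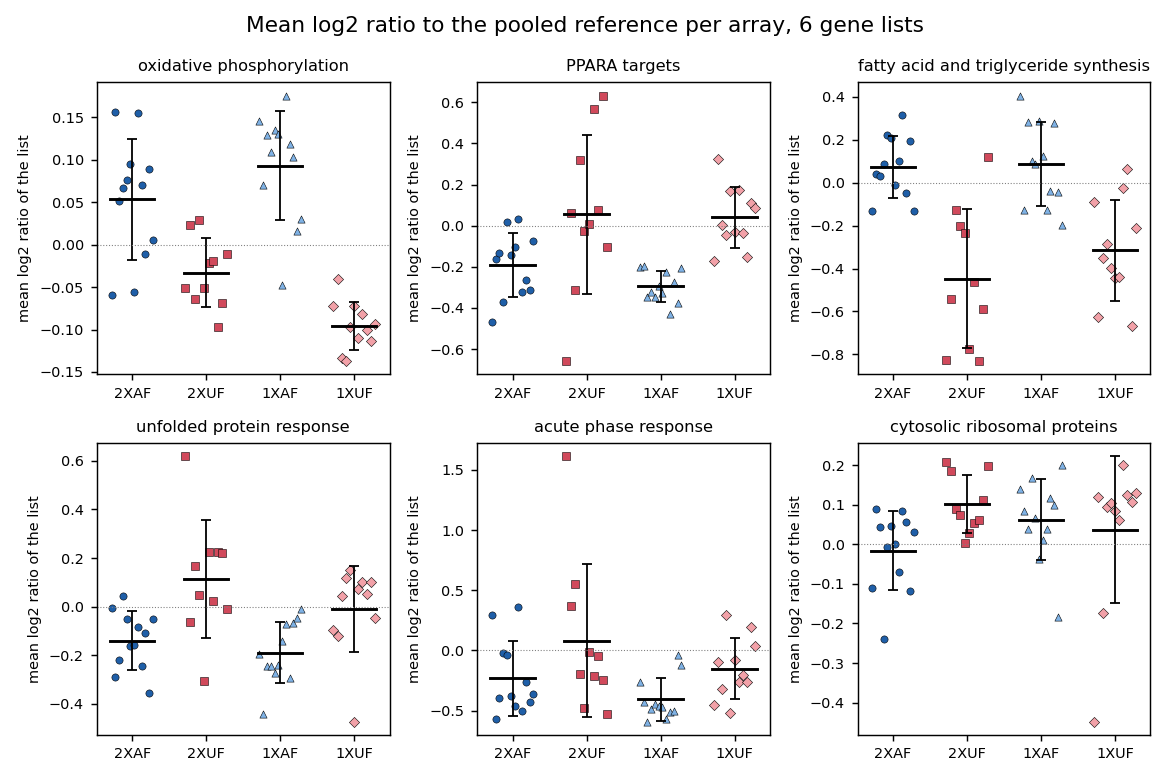
Mean log2 ratio to the pooled reference over the measured members of 6 gene lists, with 1 point per array, the group mean as a thick line and the SD as bars (2XAF n = 12, 2XUF n = 10, 1XAF n = 12, 1XUF n = 11). The oxidative phosphorylation mean was 0.053 in 2XAF, -0.033 in 2XUF, 0.093 in 1XAF and -0.096 in 1XUF, and the highest point of the acute phase panel, at 1.61, is replicate 1 of 2XUF.

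The feeding response was then taken at each milking frequency. At 2X milking the largest rises were those of GPX3 (2.39, SE 0.38), ANGPTL4 (2.00, SE 0.29) and MT2A (2.00, SE 0.32) and the largest falls those of SCD (-2.16, SE 0.47), THRSP (-1.91, SE 0.30) and FADS2 (-1.85, SE 0.32), from 10 UF and 12 AF arrays. At 1X milking ANGPTL4 (2.15, SE 0.28), GPX3 (1.93, SE 0.37) and APOA4 (1.79, SE 0.46) rose the most and SCD (-2.13, SE 0.46), THRSP (-1.83, SE 0.29) and TMED6 (-1.55, SE 0.24) fell the most, from 11 UF and 12 AF arrays. PC rose by 0.68 (SE 0.14, limma adjusted p = 0.00109) at 1X and differed by 0.38 (SE 0.14, adjusted p = 0.123) at 2X, while the test of the difference between these values gave adjusted p = 0.813. By limma 799 probes passed at 2X (441 higher, 358 lower) and 1836 at 1X (1043 higher, 793 lower). On scan day 1 alone the counts were 360 and 936, on scan day 2 alone 5 and 0, and with the sample channel alone 333 and 988.

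The feeding changes at the 2 frequencies resembled each other across genes, and they share no array. Of the 799 probes that passed at 2X, 774 had the same sign at 1X, and 482 passed at both, 264 higher and 218 lower, with 0 in opposite directions. Independent lists of these sizes would share 29.1 higher and 18.0 lower. Across the 15811 probes the log2 changes correlated with r = 0.648 (SD 0.0741 over 100 resamplings of the arrays), and by rank with rho = 0.516. After allowing for noise r was 0.933, a value for which no spread was computed. Genes are not independent replicates, so this is a description across genes. On scan day 2 alone, with 13 arrays, r was 0.316.

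**Figure D4:**
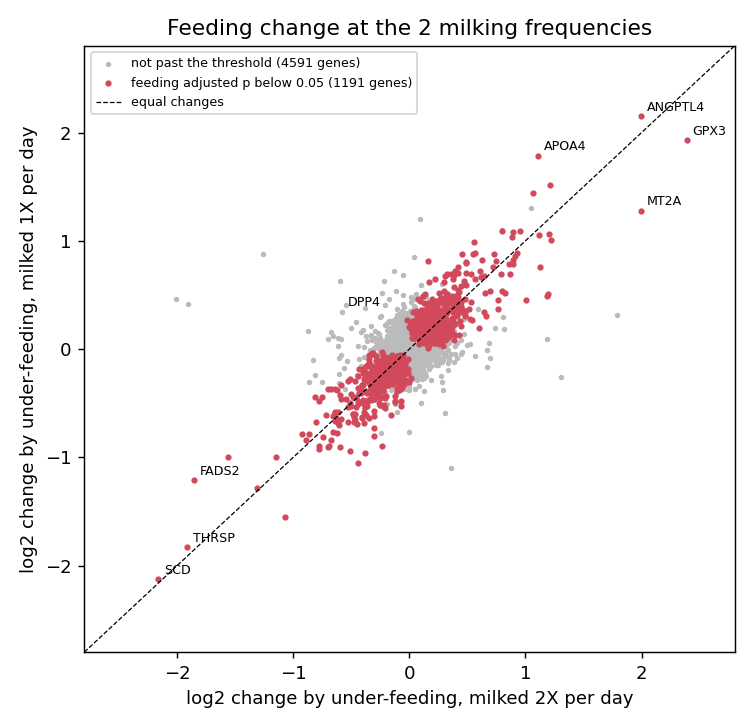
Log2 change by under-feeding at 2X milking (horizontal axis) against that at 1X milking (vertical axis), 1 point for each of 5782 genes, with the dashed line marking equal changes. Of the 1191 genes whose plotted probe passed the feeding test (red), 1189 had the same sign at both frequencies. That test uses the mean of both changes, which favours equal signs, so the count does not measure how alike the responses are. The labels name genes given in the text.

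The interaction asked directly whether milking frequency altered the response to restriction, as the difference between the feeding change at 1X and at 2X. No transcript passed. The genes with the smallest p were DTD1 (-0.22, SE 0.05), NOSTRIN (-0.53, SE 0.12), DPP4, a cell surface peptidase (0.93, SE 0.24), VBP1 (-0.24, SE 0.07) and TAF6 (0.23, SE 0.06), each with limma adjusted p = 0.69. DPP4 averaged 0.29 in 2XAF, -0.29 in 2XUF, -0.27 in 1XAF and 0.07 in 1XUF. Of the genes that responded most to feeding, the interaction was -0.46 for GPX3 (95% interval -1.52 to 0.60), 0.15 for ANGPTL4 (-0.67 to 0.97), 0.04 for SCD (-1.29 to 1.37) and 0.08 for THRSP (-0.76 to 0.93).

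By limma 0 of 15811 probes passed for the interaction, 1064 had an unadjusted p under 0.05, and the count was 0 in each of the 18 alternative settings tried, including slide or scan day as a block and each scan day alone. Some of these settings could hardly differ. Normalization of brightness between arrays leaves the log ratios unchanged, and scan day 2 alone, with 13 arrays, also gave 0 probes for feeding at 1X. The 95% interval of the interaction reached 0.203 log2 units to either side in the middle probe of those changed by feeding. It excluded a difference as large as the feeding change itself for 410 of the 2894 probes that feeding changed, and for 28 of the 35 that feeding changed by over 2-fold. In simulated data an interaction of 0.25 log2 units was recovered for 35.8% of probes, one of 0.5 for 73.1% and one of 1 for 95.5%. Those data mixed all sizes, and larger changes loosen the adjusted threshold. Recovery of small changes may thus be overstated where no probe passes.

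Transcripts for oxidative phosphorylation and for cytosolic ribosomal proteins were the lists that camera called for the interaction. The oxidative phosphorylation members lay lower at 1X than at 2X in their feeding change by a median of -0.11 (adjusted p = 3.65e-09, and adjusted p = 0.228 with an estimated correlation). Their mean log2 ratio went from 0.053 ± 0.071 (SD, n = 12) in 2XAF to -0.033 ± 0.041 (n = 10) in 2XUF, and from 0.093 ± 0.064 (n = 12) in 1XAF to -0.096 ± 0.028 (n = 11) in 1XUF. Each of the 60 members alone missed the threshold, also adjusted over the list alone, with NDUFA4 (-0.27), ATP5F1E (-0.21), ATP5PO (-0.20) and NDUFA6 (-0.15) having the smallest p. The cytosolic ribosomal proteins differed by a median of -0.16 (adjusted p = 4.77e-10, and adjusted p = 0.89 with an estimated correlation), again with 0 of 54 members past the threshold, also adjusted over the list alone, and RPL26 (-0.26), RPL30 (-0.18), RPL10A (-0.23) and RPL24 (-0.21) having the smallest p.

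The means of these lists per array gave two-sided permutation p = 0.00245 for oxidative phosphorylation (adjusted over 29 lists p = 0.071) and p = 0.054 for cytosolic ribosomal proteins (adjusted p = 0.784). With slide as a block the camera adjusted p was 8.7e-07 for oxidative phosphorylation and 7.66e-10 for cytosolic ribosomal proteins, with scan day as a block 4.71e-09 and 8.21e-11, on scan day 1 2.15e-07 and 2.87e-11, and on scan day 2 0.0743 and 0.26. With the sample channel alone the ribosomal list gave adjusted p = 0.349. Of 100 regroupings, 95 gave camera calls for as many lists as the interaction did.

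Milking frequency alone asked whether 1 milking a day changed the liver transcriptome. No transcript passed in the average over both feeding levels, from 23 arrays at 1X and 22 at 2X. The smallest p belonged to CDKN1A, a cell cycle inhibitor (0.43, SE 0.10, limma adjusted p = 0.377), followed by CPB2 (-0.24), CYP3A28 (-0.31), STAM (-0.11) and UAP1 (-0.18), each with adjusted p = 0.949. CDKN1A averaged -0.31 ± 0.34 (SD, n = 12) in 2XAF, 0.06 ± 0.35 (n = 10) in 2XUF, 0.26 ± 0.30 (n = 12) in 1XAF and 0.36 ± 0.33 (n = 11) in 1XUF. PC differed by -0.22 (SE 0.10, adjusted p = 0.949) and GHR by 0.18 (SE 0.10, adjusted p = 0.949).

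By limma 0 of 15811 probes passed for milking, with 747 at an unadjusted p under 0.05. Within adequately fed cows 0 passed (794 unadjusted) and within under-fed cows 0 (1080 unadjusted). The count for milking was 0 with slide as a block and with scan day as a block, and 1 on each scan day alone. In simulated data a milking change of 0.25 was recovered for 80.6% of probes and one of 0.5 for 97.0%. Larger changes were simulated alongside, which loosens the adjusted threshold, so these shares may be too high where no probe passes.

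As lists, acute phase response lay lower at 1X (median -0.16, camera adjusted p = 0.00123, and adjusted p = 0.975 with an estimated correlation) and cholesterol synthesis higher (median 0.12, adjusted p = 0.00937, and adjusted p = 0.975 with an estimated correlation). None of the 19 and 17 members passed alone, also adjusted over the list alone. Among the acute phase members with the smallest p were IL1RN (-0.22), C4BPA (-0.16), LBP (-0.43) and FGA (-0.24), and among those of cholesterol synthesis MVD (0.21), SQLE (0.38) and DHCR7 (0.27). In the permutation test of the list means no list passed for milking, and these 2 gave p = 0.071 and p = 0.315 (each adjusted p = 0.889).

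With slide as a block the adjusted p was 0.00537 for acute phase response and 0.0351 for cholesterol synthesis, and with scan day as a block 0.00137 and 0.0186. On scan day 1 both kept their direction (1.29e-08 and 0.00339). On scan day 2 acute phase response was higher at 1X (adjusted p = 0.000202) and cholesterol synthesis gave 0.923. With the sample channel alone they gave 0.507 and 0.179, and with array weights 0.0334 and 0.0593. Without replicate 1 of 2XUF the milking difference of the acute phase list mean was -0.119, against -0.204 with it. Of 100 regroupings, 94 gave camera calls for as many lists as milking did.

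Transcripts of milk proteins, which are not known as liver products, were found on the arrays and differed between milking frequencies as a group, which was looked at only after their spread had been seen. The mean of 6 such transcripts (CSN1S1, CSN1S2, CSN3, LALBA, PAEP and GLYCAM1) was lower at 1X by -1.34 (SE 0.40, two-sided permutation p = 0.00115), on 10 of 11 slides, and by -1.37 (SE 0.43) with slide as a block. The size is limited by background, since all 6 were well above it on 20 of 22 arrays at 2X and 9 of 23 at 1X. GLYCAM1, well above background on all 45 arrays, was lower by -0.84 (SE 0.26, two-sided permutation p = 0.00106). It followed the mean of the 6 with r = 0.98, so it is not separate support. Each of the 6 alone had limma adjusted p = 0.949 for milking, and the permutation p values are not adjusted for the choice of these transcripts.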

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

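The tests of list means by permutation, of single arrays and of scan days, and the use of the planned setting with the sample channel alone as a test, were chosen only after the results were seen, while the regroupings were planned and the brightness tests, run for lists already called, had their predictions written before they were run. Of the 4 groups only 2XUF, with 10 arrays, has a size for which a gap test was set, and chance marks about 1 in 20 values. There 22 of 132 genes and 7 of 29 list means held 1 array far from the other 9, and 19 of these 29 were replicate 1, which also had the lowest array weight (0.285). The value of 1 of these genes is not given here. In that cow's liver the acute phase list mean stood high at 1.61 (FGA at 2.35), the T and NK cell mean at 0.87, the neutrophil mean at 0.79, and the cell cycle mean at 0.79 (PRC1 at 1.25, MCM3 at 0.98, PLK1 at 0.79 and AURKA at 0.71). The fatty acid oxidation mean stood low at -0.66 (DECR1 at -1.08, ACAA1 at -0.36), as did the xenobiotic metabolism mean at -0.75. Single genes of other lists stood at 1.09 (FABP3), 0.49 (GABARAP), -1.35 (SLC10A1), -0.74 (APOC2) and -0.72 (GABARAPL1).

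Other arrays of 2XUF stood apart in single values. Replicate 3 lay low in ATP5F1A (-0.52) and ATP5MC3 (-0.37) and high in CTSD (0.33). Replicate 9 lay high in PDK4 (2.53), SLC22A5 (1.3) and POSTN (0.39). Replicate 4 lay high in GHR (0.47) and low in the endothelial cell mean (-0.5), replicate 5 lay high in PRLR (0.93) and replicate 7 low in DPP4 (-1.41). Arrays of the other groups were not searched with the gap test. Among them replicate 1 of 1XUF had a hepatocyte mean of -0.763, against 0.049 in the next array of its group.

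A pattern weighed here is the acute phase list, which lay higher with under-feeding (camera adjusted p = 0.0218, and adjusted p = 0.85 with an estimated correlation) and lower at 1 milking a day (0.00123, and adjusted p = 0.975 with an estimated correlation). Replicate 1 of 2XUF as the whole source of the feeding difference of the list mean is argued against: the mean shift was 0.284 (SE 0.119, p = 0.00889) with it and 0.199 (SE 0.087, permutation p = 0.0237) without it. Both p values are of the permutation test and are not adjusted over the lists. The camera call for feeding was lost without that array, so the call itself depends on it. For the milking difference the shift went from -0.204 (SE 0.119) to -0.119 (SE 0.087, p = 0.167), which leaves open whether that array may be its source. A milking difference that is alike on both scan days is argued against, at -0.372 on day 1 and 0.266 on day 2 (permutation p of the difference = 0.00042). The milking difference is also open to members that vary together, with p = 0.071 for the list mean, as is that of cholesterol synthesis, with p = 0.315.

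Another pattern is the difference in the feeding change between milking frequencies for oxidative phosphorylation (camera adjusted p = 3.65e-09, and adjusted p = 0.228 with an estimated correlation) and cytosolic ribosomal proteins (4.77e-10, and adjusted p = 0.89 with an estimated correlation). A trend of the ratio with probe brightness is argued against: 0 of 10000 random lists of matched brightness had a median as low as -0.106 for oxidative phosphorylation (95% of them from -0.059 to 0.023), and 0 of 10000 as low as -0.156 for ribosomal proteins (-0.113 to -0.029). The random lists matched to the ribosomal proteins had a median of -0.072 themselves, so brightness may account for part of the -0.156 but is argued against as the whole, and without replicate 1 of 1XUF 0 of 10000 were as low as the -0.107 then left (-0.069 to 0.013). The ratio to the pool and its normalization is argued against for oxidative phosphorylation, whose median was -0.09 with the sample channel alone (adjusted p = 0.000461), and stays open as a source for ribosomal proteins, at -0.03 (adjusted p = 0.349). Members that vary together could account for the ribosomal call (p = 0.054 for the list mean), a list in which replicate 1 of 1XUF stood lowest and which gave adjusted p = 5.94e-05 without it, while for oxidative phosphorylation p = 0.00245, or 0.071 adjusted over the lists, leaves this undecided. A larger fall of respiratory chain transcripts in cows milked 1X, the biological reading, therefore stays a hypothesis.

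Regroupings of the arrays into groups of the same sizes were drawn 100 times for each count, the real one included. Chance is argued against for the probes changed by feeding, where 1 of 100 gave as many (the real 2894, with 1 as the highest other). The same holds for feeding at 2X (1 of 100, 799 against 3) and at 1X (1 of 100, 1836 against 404). A share of 1 of 100 is the smallest that 100 regroupings can give. Where the real count is 0 every regrouping gives as many, so the comparison says nothing on chance for milking (100 of 100, highest other 314), the interaction (100 of 100, highest other 2), milking in adequately fed cows (100 of 100, highest other 1) or milking in under-fed cows (100 of 100, highest other 53). Chance can not be excluded for the number of lists called by camera, where 32 of 100 gave as many as feeding (8, highest other 16), 94 as many as milking (2, highest other 16) and 95 as many as the interaction (2, highest other 14). The median of the other regroupings was 6 lists for feeding, for milking and for the interaction. The 2 lists called for milking and the 2 for the interaction were thus fewer than a regrouping usually gave. Camera at the preset correlation called lists too readily on these arrays. Of the 99 regroupings drawn for feeding at 1X, the one with 404 probes followed the real feeding groups, in reverse, the most closely, so it carries part of the feeding difference. Those with 314 and 53 probes kept feeding level balanced or fixed and, of the 99 drawn for each, followed the third (314) or first (53) principal component the most closely, which may reflect a structure of the samples within feeding levels. For milking in under-fed cows, those with 38 and 20 probes followed no component the most closely, with 2 and 4 of 99 as far along the second. How the regroupings lay was looked at after their counts were seen.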

How the results depend on the processing

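Scan day, leaving out replicate 1 of 2XUF and leaving out replicate 1 of 1XUF were chosen after the data were seen. The other alternatives were planned. For each count of probes, 16 to 19 of the settings tried kept it within 1.5 times or at 0. The median of all probes stayed within 0.01 of 0 in every contrast. Normalization of the arrays brings that median near 0 by itself, so it says nothing on how stable the results are. Among the settings counted here, normalization of brightness between arrays leaves every log ratio as it was, so its results could not move. The interaction stayed at 0 probes in limma in all 18 settings, with 647 to 1491 probes at an unadjusted p under 0.05. Of 24 genes with the largest feeding changes 21 passed in 18 of 19 settings and 3 in all 19, the exception being scan day 2 alone.

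With the sample channel alone, feeding changed 1858 probes, 333 at 2X and 988 at 1X, keeping 1720 of the 2894 calls, and milking shifted 0 lists; the cause was not tested. Scan day 1 alone, with fewer arrays, gave 360 probes for feeding at 2X, 936 at 1X and 1 for milking. Scan day 2 alone, with 13 arrays, gave 80 for feeding, 5 at 2X, 0 at 1X, 1 for milking and 1 for milking in under-fed cows, lists of 5 for feeding, 1 for milking and 1 for the interaction, and r = 0.316 between both feeding changes. That interaction list was bile duct cell markers, called in 2 of 17 alternatives and at camera adjusted p = 0.337 in the main fit. PLK1 turned on scan day 2 from 0.18 to -0.01 (adjusted p = 0.968). An estimated inter-gene correlation left 1 list for feeding, 0 for milking and 0 for the interaction, since it widens the error of a list. Milking shifted 4 lists without background correction, 4 with the scanner's ratio, 4 without 2XUF replicate 1 and 5 without 1XUF replicate 1, and the scanner's ratio gave r = 0.553; the cause was not tested.

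For named genes in the feeding contrast, 2311 of 2497 values kept direction and call, 135 lost the call (83 of them on scan day 2 alone) and 30 gained it. CLOCK, NFIL3 and ITIH3 lost it in more than 1 setting that used all arrays. Replicate numbers gave no clear pairing of the cows: residuals of same-numbered arrays correlated with a mean r of 0.0435, 22 of 64 pairs were over 0.1, and 7 of 45 arrays matched their own number best. Arrays of other numbers had a mean r of -0.00385. Arrays of 1 slide were somewhat more alike, with a mean r of 0.0703 against -0.00772 on other slides. Of 45 arrays, 12 matched an array of their own slide best. With the replicate block the counts were 3172 for feeding, 0 for milking, 0 for the interaction, 939 and 2109 for feeding at 2X and 1X, 0 and 0 for milking within AF and UF, lists of 10, 2 and 2, and r = 0.674. Signal over background limited the tested probes to 15811 of 21475, with 15202 well above it on the median array.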

Other observations

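The tests on milk protein transcripts were all chosen only after their spread had been seen, and the list of mammary markers was written after FABP3 had been seen to follow them. Among lists not described so far, cell cycle transcripts leaned lower in under-fed cows: of 19 measured members 2 fell, 1 rose and 16 did not pass (3 and 1 adjusted over the list alone), with camera adjusted p = 0.0526 and adjusted p = 0.857 with an estimated correlation. AURKA (-0.34, SE 0.07) and PRC1 (-0.32, SE 0.10, with slide as a block adjusted p = 0.0573), a kinase and a microtubule protein of mitosis, fell, PLK1 (0.18, SE 0.06, with array weights adjusted p = 0.165) rose, and MCM3, of the replication helicase, differed by -0.20 (adjusted p = 0.0513). Without replicate 1 of 2XUF, in which these transcripts were high, the cell cycle list gave adjusted p = 0.000177 and MCM3 -0.27 (adjusted p = 0.00036). By batch the cell cycle list gave 0.184 with slide as a block, 0.0653 with scan day as a block, 0.345 on scan day 1 and 0.00235 on scan day 2, and its mean was lower in the under-fed arrays on 10 of 11 slides. It leaned down in all 18 alternatives and passed in 7, with adjusted p from 0.000177 to 0.622, among them array weights (0.000571), the sample channel alone (0.0174) and the scanner's ratio (0.00706), which gave a median of -0.539 against -0.112.

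Cytosolic ribosomal proteins had camera adjusted p = 0.0932 for feeding (median 0.046, 4 of 54 up and 1 down, 0 and 1 adjusted over the list alone), and adjusted p = 0.869 with an estimated correlation. The list leaned up in all 18 alternatives and passed in 9 of them, with adjusted p from 3.14e-05 to 0.4: 0.0368 with slide as a block, 0.0479 with scan day as a block, 0.4 on scan day 1, 3.14e-05 on scan day 2 and 0.0011 without replicate 1 of 1XUF. RPL7 (-0.21), RPS29 (0.14), RPS28 (0.16) and RPL29 (0.15) had the smallest p. In extracellular matrix (adjusted p = 0.487) POSTN (-0.33, SE 0.11) and SPARC (-0.30, SE 0.10, with slide as a block adjusted p = 0.051) fell and 14 of 16 did not pass, also adjusted over the list alone. In autophagy and lysosome (adjusted p = 0.971) GABARAP (0.24, SE 0.04) and CTSD, cathepsin D (0.13, SE 0.04), rose (with the sample channel alone adjusted p = 0.0677 and 0.0604) and 19 of 21 did not pass, also adjusted over the list alone, and GABARAPL1 differed by -0.19 (adjusted p = 0.0951). The proteasome list gave adjusted p = 0.459, with 1 of 26 members up and 2 down, and the interferon response 0.86, with 0 of 10 past the threshold, both also adjusted over the list alone.

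Milk protein transcripts varied widely between the livers. CSN1S1, alpha-S1-casein, ranged from -4.33 to 3.56 over the 45 livers, the low end being limited by background, which it was well above on 39 arrays, and CSN1S2, CSN3, LALBA, PAEP and GLYCAM1 followed it, with pairwise r of 0.952 to 0.99 among the 6. CSN3 and CSN1S1 correlated with r = 0.989 and rho = 0.979 (each permutation p = 1e-05, the smallest 100000 permutations can give, adjusted p = 1e-05 over the 2 relations), with r = 0.985 without the 2 farthest arrays and 0.987 and 0.99 within the scan days. CSN3 and FABP3 correlated with r = 0.724 (p = 1e-05, adjusted p = 1e-05) and rho = 0.557 (p = 5e-05), 0.61 without the 2 farthest arrays and 0.643 and 0.856 within the scan days.

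Carry-over between arrays of a slide stays undecided: CSN1S1 ranged by 2.34 to 6.5 log2 units within the 11 slides of 4 arrays, with low ends also limited by background, which leaves room for a small share from a high array, and the other arrays of a slide were not shown to be higher where its highest array was higher (one-sided permutation p = 0.15). RNA of mammary tissue or milk cells in the samples, taken up at biopsy or handling, may be the source but stays undecided: 8 other mammary markers, 7 of them well above background on all arrays and 2 also in another list, followed the milk protein mean with a median r of 0.074, above 81.8% of random lists of matched brightness, and the slopes of the milk protein signals against each other were 0.614 to 1.02. The mean of the milk protein transcripts was lower at 1X by -1.34 (interval -2.14 to -0.54, permutation p = 0.00115). It was lower by -1.47 on scan day 1 and -0.73 on day 2, sizes that background limits. That p is not adjusted for the choice of these closely correlated transcripts, and each alone had limma adjusted p = 0.949. A link with milking frequency therefore stays tentative. A candidate explanation, as a hypothesis, is that the amount of milk-derived or mammary RNA reaching these samples, or a low expression in liver cells, differs with milking frequency. These data do not tell them apart, and in situ hybridisation for casein transcripts on liver sections, with blank extractions handled alongside the biopsies, would.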
